A study of Homo sapiens with 4 samples.

How the data were processed

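Ribosome footprints were sequenced from HAP1 cells, a near-haploid human line derived from KBM-7, of wild-type genotype. Per the labels' protocols, the cells received 1 µM of a compound named GCN2i for 1 h, then 20 µM azacytidine (aza-C) together with GCN2i for 2 h, then GCN2i alone for 2 h. Aza-C is a cytidine analogue that cells build into RNA. Lysates made with cycloheximide were digested with RNase I and separated on sucrose gradients. RNA from the monosome fraction was size-selected to 25 to 35 nt and RNA from the disome fraction to 54 to 68 nt. Monosome footprints come from single ribosomes and disome footprints from a pair of adjacent ribosomes. The labels name 2 biological replicates of each fraction, 4 libraries in all, and all 4 received the same treatment. No library of cells without aza-C was analysed here.

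The data are 1 table for the whole series, with 48 lines, 1 for each of 12 conversion types in each of 4 libraries. A conversion type is a base of the reference read as another base. Per the file headers, the deposited counts are the total reads of a library, mismatches set aside as SNPs and true conversions. The deposited percent column equals conversions per 100 reads: it was recomputed from the counts and matched within 1e-09 in all 48 lines. It counts conversions, not converted reads, and is not scaled to footprint length. The remaining columns are lists of 100 whole numbers, which the file headers call conversion positions, conversion lengths and unconverted lengths. The position list summed to the conversion count in all 48 lines. The submitters' processing notes name cutadapt 5.0, Bowtie2 2.5.0, STAR 2.7.10b and the build GRCh38 (hg38), with no role or order. How conversions were called, how SNPs were recognised and which reads were counted is not given in the sources used here. The table holds no genes or genomic coordinates, so no gene is named.

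Neither the header nor the labels state where positions are counted from. The first entry of a position list was taken as nucleotide 1 at the 5′ end of the footprint, and all nucleotide numbers below rest on that reading. The first 2 entries were 0 for every type and library, as was the last nucleotide of the longest footprints, and these were left out of averages and tests by position. Rates per footprint nucleotide divide by the full mean length, so these blank nucleotides stay in the divisor. They are a greater part of the shorter monosome footprints, which raises disome folds per nucleotide somewhat. The entry number of the length lists was taken as the length in nt. A position rate is conversions per 10000 reads that reach the nucleotide, with the reach taken from the length lists and scaled to total reads. Interior nucleotides are those not within 3 nt of either end of the shortest listed footprint, nucleotides 4 to 25 of monosome and 4 to 55 of disome footprints. The lists give positions over all footprint lengths together, so windows counted from the 3′ end were averaged over the lengths and are approximate.

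The C-to-G rate was compared between disome and monosome libraries on the log2 scale with an exact two-sided permutation test. With 2 against 2 libraries this test has 6 assignments and its smallest p is 0.333. C-to-G was also set against the median of the other 11 types with an exact sign-flip permutation test over 4 libraries, whose smallest p is 0.125. All 12 types, and 348 combinations of nucleotide and type shared by both fractions, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 rates, Benjamini-Hochberg adjustment, threshold 0.05). Combinations needed 10 conversions over the 4 libraries, and 0.5 was added to each position count. The position profile of each fraction was fitted with limma on log2 rates relative to the library's interior median. limma on log2 rates was fixed before the values were known to be counts, so the quasi-likelihood test of edgeR 4.0.16 on the conversion counts was added. limma treats the 12 types as separate features that share an estimate of spread, and a shift common to the types of a library can make its p-values too small. In the disome profile it used 1 spread for all 63 nucleotides, with 63 degrees of freedom from 2 libraries, against 1.89 in the main monosome profile. Neighbouring nucleotides of a library are not independent, so the disome profile p-values can be far too small. The same applies to the monosome fit over the G-to-C rate. Remaining steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

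Before the data were examined, the groups, tests, site windows, named items and most alternatives were fixed. The named types were C-to-G, G-to-C, C-to-T and C-to-A, and the 3 types with the greatest absolute log2 difference. The named positions were, per fraction, the 3 highest and 3 lowest interior C-to-G rates, the first and last 3 nucleotides as groups, and the windows. Windows from the 5′ end were nucleotides 10 to 12 for the ribosomal E site, 13 to 15 for the P site and 16 to 18 for the A site. Windows from the 3′ end were nucleotides 11 to 13 for the A site, 14 to 16 for the P site and 17 to 19 for the E site. Alternatives left out each library, took the replicate number as a block, used interior positions, subtracted G-to-C, changed the scale or summary, changed the count minimum to none or 50, centred each library on its median, or shifted the windows by 1 nt. Rates per footprint nucleotide, per read in the length lists, over interior medians and outside the peaks were added after seeing the data, as was edgeR.

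The limma steps were tested on simulated data in 20 simulations each. With 3 of 12 types changed 3-fold, 100% were recovered and 1.67% of unchanged types were called. With 60 of 348 combinations changed 3-fold, 97.9% were recovered and 1.46% of the others were called. With 5 of 63 disome nucleotides raised 4-fold, 100% were recovered and 0.259% of the others were called. The simulated replicate noise was independent between features.

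Total reads were 2963487 and 2260837 in the monosome libraries and 423265 and 391863 in the disome libraries. The disome libraries are the shallower ones and limit the precision of position rates. Wilson 95% intervals are given for shares of converted reads and shares of conversions at a nucleotide, not for conversions per 100 reads, since a read can carry several conversions. They cover counting error only, since reads copied by PCR are not independent molecules. The replicates of a fraction differed by more than sampling noise over the 12 types (chi-square 1928 for monosomes and 702 for disomes, df 11), so none was counted as a duplicate.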

Results

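Mismatches of 12 conversion types were counted in ribosome footprints of HAP1 cells treated with azacytidine (aza-C). There were 2 libraries of monosome footprints and 2 of disome footprints, with 2963487 and 2260837 reads in the first pair and 423265 and 391863 in the second. Listed footprints were 28 to 32 nt long in monosome and 58 to 66 nt in disome libraries, with means of 30.5 and 62.6 nt. Aza-C built into RNA can be read as G when the RNA is copied to cDNA, so C-to-G conversion was taken as its mark. The series title concerns aza-C damage to mRNA, and the comparison of the fractions asks where converted bases lie relative to single and paired ribosomes. All libraries came from treated cells, so no rate below is set against untreated cells.

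C-to-G conversions were more frequent in disome than in monosome footprints. They occurred at 10.9 ± 2.32 per 100 reads in disome libraries and 2.61 ± 0.356 in monosome libraries (mean ± SD, n = 2 each). Disome replicate 1 had 12.5 per 100 reads and replicate 2 had 9.23. Monosome replicate 1 had 2.86 and replicate 2 had 2.35. The disome rate was 4.14-fold the monosome rate, a log2 difference of 2.05 against a pooled SD of 0.26 between replicates. The exact two-sided permutation test gave p = 0.333, the smallest it allows with 2 against 2 libraries. Disome footprints are 2.05 times as long, and per footprint nucleotide the fold was 2.02. That rate divides by the full length with its blank end nucleotides, which raises the fold somewhat. Outside nucleotides 44 to 52 of disome and 16 to 20 of monosome footprints it was 1.41, with rates of 13.03 ± 2.61 and 9.20 ± 1.12 conversions per 10000 reads and nucleotide.

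Reads with any conversion made up 18.9 ± 2.33% of listed disome reads and 6.13 ± 0.233% of listed monosome reads (SD, n = 2 each). The 95% Wilson intervals were 20.4 to 20.7% and 17.2 to 17.4% for disome replicates 1 and 2, and 6.27 to 6.32% and 5.935 to 5.998% for monosome replicates 1 and 2. All conversions over converted listed reads came to 1.35 ± 0.0517 in disome and 1.11 ± 0.00533 in monosome libraries. These ratios are too high if conversions were also counted in reads outside the length lists, 11.5% of disome and 2.85% of monosome reads.

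The 3 types from C made up most conversions in both fractions, 77.3 ± 3.21% in disome and 66.9 ± 3.77% in monosome libraries (SD, n = 2 each, SNPs left out). C-to-G alone made up 47.7 ± 3.18% and 39.3 ± 4.04%. All 3 types from C, all 3 from A, all 3 from G and all 3 from T were higher per read in disome footprints. That is 12 higher and 0 lower at a limma adjusted p under 0.05, and likewise 12 and 0 with edgeR. Per footprint nucleotide 6 were higher and 3 lower, and relative to each library's median over types 4 were higher and 4 lower, a balance that this centring sets by construction. The median type was 2.52-fold higher per read and 1.23-fold higher per nucleotide, a log2 shift of 1.33 and 0.30. Per nucleotide, the 3 types from C were higher, with C-to-A at 1.79-fold and C-to-T at 1.78-fold. By the median over interior nucleotides C-to-A was only 1.16-fold and C-to-T 1.01-fold. A-to-T, A-to-G and G-to-A were also higher per nucleotide, at 1.96-fold, 1.37-fold and 1.36-fold, but by the median over interior nucleotides A-to-T and A-to-G were lower. In disomes 4 nucleotides held 66.7 ± 3.56% of A-to-T conversions and 3 held 32.9 ± 1.17% of A-to-G (SD, n = 2). The SNPs set aside were 24.2% of G-to-A and 25.1% of A-to-G mismatches in monosome libraries. In disome libraries they were 13.1% and 16.8%, so part of these 2 folds can come from that step. The same holds for C-to-T, with 14.4% set aside in monosome and 7.80% in disome libraries. G-to-C, the complement of C-to-G, was 0.775-fold, T-to-A 0.778-fold and T-to-G 0.644-fold, where T-to-A missed the threshold with edgeR (adjusted p = 0.060). The SNP share of T-to-A was higher in disome than in monosome libraries, 16.9 against 13.4%. For T-to-G it was 29.3 against 21.5%, and both differences can lower the folds of these types. Transitions were higher per nucleotide in 3 of 4 types, and transversions were higher in 3 of 8 and lower in 3.

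The 3 types with the greatest differences per read were C-to-G, A-to-T and C-to-A. In the limma fit C-to-G had a log2 difference of 2.05 (SE 0.16, adjusted p = 3.57e-11) and A-to-T of 2.01 (SE 0.16, adjusted p = 3.57e-11). C-to-A had 1.87 and C-to-T 1.87 (SE 0.16 each, adjusted p = 8.07e-11 each). G-to-C had 0.67 (SE 0.16, adjusted p = 4.00e-04). In every case both disome libraries lay above both monosome libraries. Without disome replicate 1 or without disome replicate 2, limma called 0 types higher and 0 lower per nucleotide, with 2 and 3 types at an unadjusted p under 0.05. C-to-G had log2 differences per nucleotide of 0.80 and 1.23 there, against 1.01 with all libraries, with limma adjusted p = 0.197 and 0.106. The disome arm then held 1 library, and without monosome replicate 2 the types lower per nucleotide fell to 1.

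**Figure D1:**
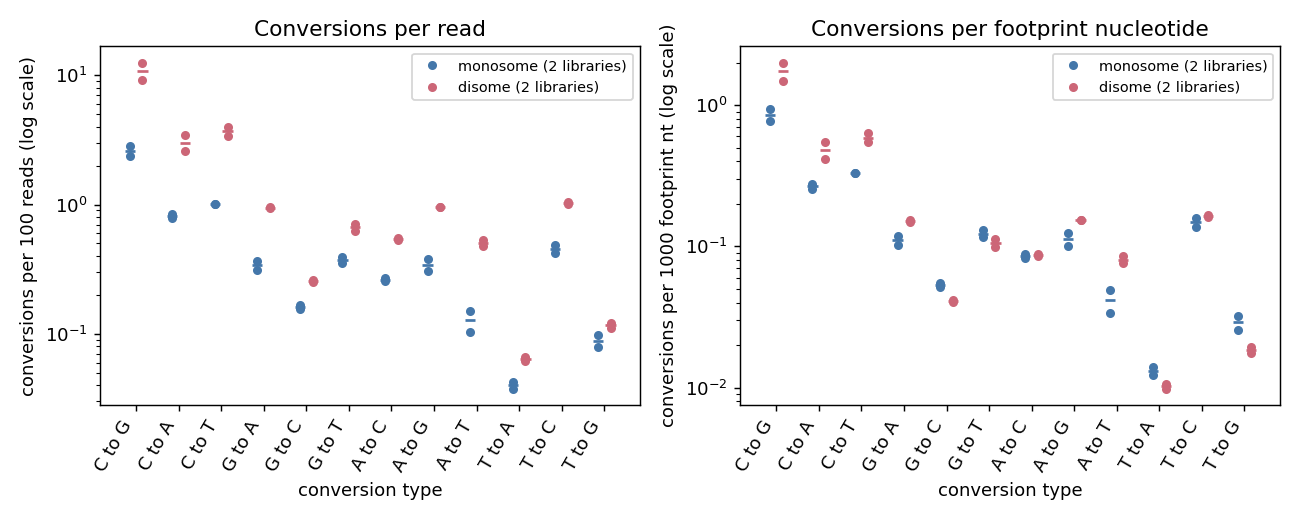
Conversions of each type per 100 reads (left) and per 1000 footprint nucleotides (right), both on log axes, with 1 point per library and a short line at the mean of 2 libraries. C-to-G is the most frequent type in both fractions, at 10.9 per 100 reads in disome and 2.61 in monosome libraries, and G-to-C in disome libraries is higher per read and lower per nucleotide.

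Within libraries, C-to-G was compared with the background of the other 11 types. It exceeded their median 9.34-fold and 6.65-fold in the monosome libraries and 17.8-fold and 14.8-fold in the disome libraries. Over 4 libraries the mean log2 ratio was 3.50, and it lay above 0 in all 4 (exact two-sided sign-flip permutation p = 0.125, the smallest possible). Against G-to-C alone, which aza-C in the sequenced strand does not give, C-to-G was 16.2 ± 2.93-fold in monosome and 42.3 ± 10.1-fold in disome libraries (SD, n = 2 each).

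In monosome footprints, C-to-G conversions formed a low peak at nucleotides 17 to 19. The rate at nucleotide 18 was 17.2 ± 3.43 per 10000 reads (SD, n = 2), which was 1.72-fold the interior median (log2 0.78, SE 0.05, limma adjusted p = 0.013). Over the G-to-C rate at the same nucleotide the log2 value was 1.56 (limma adjusted p = 4.92e-11). The G-to-C rate was itself low there, 0.325 per 10000 reads against an interior median of 0.541, which raises this value. A p-value as small as 4.92e-11 from 2 libraries needs a spread shared by many neighbouring nucleotides, so it overstates the precision. Nucleotide 17 stood at 1.43-fold and nucleotide 19 at 1.42-fold. These 3 nucleotides held 17.5 ± 1.10% of C-to-G conversions on 10.3% of the nucleotides listed. Of 29 nucleotides tested by limma, 8 lay above the interior median, nucleotides 10 to 12 and 16 to 20, and 12 lay below it. Over the G-to-C rate at the same nucleotide, 5 lay above and 12 below, and against the mean over all positions 14 lay above and 9 below. The lowest interior rates were at nucleotides 4, 5 and 6, at 0.390, 0.523 and 0.767 of the interior median. Of the first 3 nucleotides only nucleotide 3 had conversions listed, at 2.40 ± 0.00296 per 10000 reads, and of the last 3 of the longest footprints nucleotides 30 and 31, which averaged 2.77 ± 0.491 (SD, n = 2).

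In disome footprints, C-to-G conversions were concentrated in a sharp peak at nucleotides 47 to 49. The rate at nucleotide 48 was 102.0 ± 23.6 per 10000 reads (SD, n = 2), which was 7.36-fold the interior median (log2 2.88, SE 0.07, limma adjusted p = 2.71e-44). The SE and p-value rest on 1 spread shared by 63 neighbouring nucleotides of 2 libraries, so they overstate the precision. Over the G-to-C rate at the same nucleotide the log2 value was 2.16 (limma adjusted p = 1.48e-06). The G-to-C rate was raised there, 0.654 per 10000 reads against an interior median of 0.392, which lowers this value. Nucleotide 49 stood at 5.99-fold and nucleotide 47 at 5.40-fold. These 3 nucleotides held 23.9 ± 0.689% of C-to-G conversions on 4.76% of the nucleotides listed. Of 63 nucleotides tested by limma, 13 lay above the interior median, all at nucleotides 42 to 54, and 19 lay below it. Against the mean over all positions 9 lay above and 51 below, and over the G-to-C rate 7 lay above and 7 below. The lowest interior rates were again at nucleotides 4, 5 and 6, at 0.298, 0.486 and 0.719 of the interior median. At the ends, nucleotide 3 had 1.45 ± 0.459 per 10000 reads, and nucleotides 64 and 65 averaged 5.14 ± 0.846 (SD, n = 2), while nucleotides 1, 2 and 66 had no conversion of any type listed. The disome peak lay 30 nt downstream of the monosome peak.

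**Figure D2:**
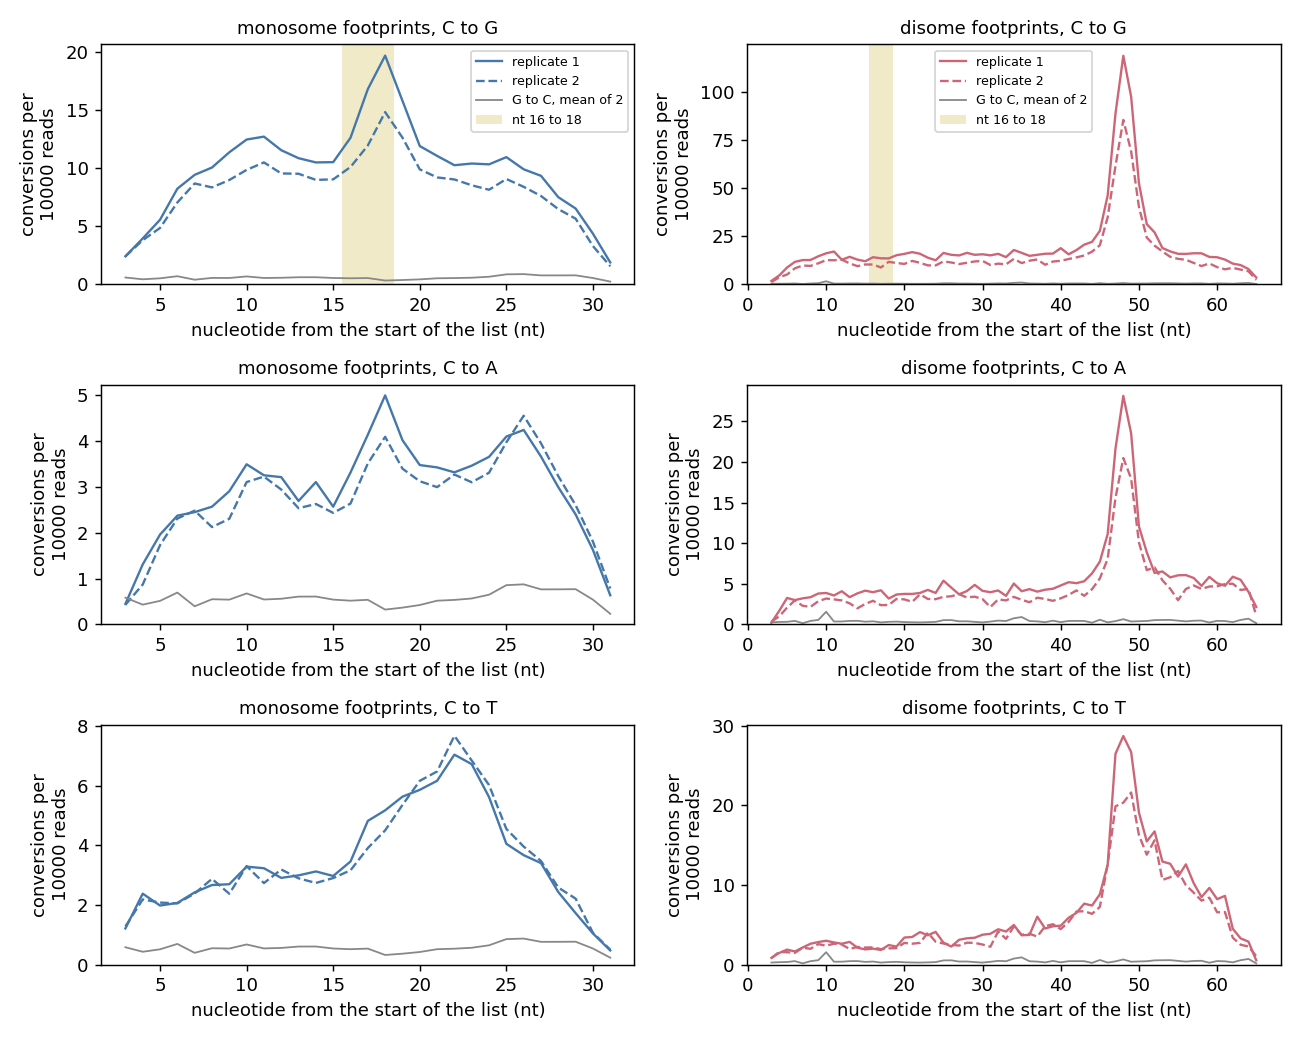
Conversions per 10000 reads (vertical axis, from 0, with a different range in each panel) by nucleotide from the start of the position list (horizontal axis, nt), for C-to-G, C-to-A and C-to-T in monosome (left) and disome (right) footprints. Solid and dashed coloured lines are replicates 1 and 2, the grey line is the mean G-to-C rate and the shaded band in the top panels marks nucleotides 16 to 18; C-to-G peaks at nucleotide 18 in monosome and at nucleotide 48 in disome footprints.

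The ribosomal site windows relate these positions to the decoding sites of the ribosome. The A site is where the incoming tRNA binds. In the A site window of the 5′ end, the C-to-G rate of monosome footprints was 1.49-fold that of the other interior nucleotides. The log2 ratios were 0.65 and 0.50. The P site window had 0.967-fold and the E site window 1.10-fold. In disome footprints the same windows, which belong to the trailing ribosome, had 0.606-fold, 0.590-fold and 0.717-fold. The A site log2 ratio was -0.72 ± 0.01 in disome and 0.57 ± 0.11 in monosome libraries (SD, n = 2 each), a difference of -1.30. The exact two-sided permutation test gave p = 0.333, the smallest it allows. The peak is part of the disome reference. With the peaks of both fractions left out of the reference, the disome A site window stood at 0.911-fold. The disome P site window stood at 0.886-fold and the E site window at 1.08-fold, so the E site window turned from below to above the reference. The monosome P site window turned likewise, from a log2 of -0.05 to 0.13, and the monosome E site window rose from 0.14 to 0.33. The A site difference was then -0.76. Shifting the windows by 1 nt gave differences of -1.03 and -1.37.

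In the windows of the 3′ end, which in disomes belong to the leading ribosome, the disome rate was 2.72-fold the other interior positions in the P site window, 2.67-fold in the E site window and 2.16-fold in the A site window. The corresponding monosome values were 1.34-fold, 1.01-fold and 1.28-fold. Because positions are not separated by footprint length, these averages blur the windows. In disomes the A, P and E site windows were centred at nucleotides 51.5, 48.5 and 45.5 from the 5′ end. The windows of both ends did not pick the same site in monosomes. There the A site window was highest from the 5′ end and the P site window from the 3′ end. The site named thus depends on the end counted from. The windows of both ends cover the same nucleotides only in 28-nt footprints, 9.85 and 9.20% of listed monosome reads. In 31-nt footprints, the most frequent length, the P site window from the 3′ end is the A site window from the 5′ end. The disagreement therefore follows largely from the window definitions.

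Over the nucleotides that both fractions share, limma called 16 of 348 combinations of nucleotide and type higher and 32 lower in disome footprints. A-to-T was lower at 11 of 29 nucleotides and higher at 1. C-to-G was higher at 3, nucleotides 29 to 31, where monosome footprints end, and lower at 0. C-to-T was lower at nucleotides 17 to 19, with log2 differences of -1.19, -1.10 and -1.34, and higher at 2. The calls ranged from 2 to 39 higher and from 3 to 96 lower when single libraries were left out. They were 2 and 3 without monosome replicate 2, 5 and 13 without monosome replicate 1, 23 and 94 without disome replicate 1, and 39 and 96 without disome replicate 2. With each library centred on its median, 21 were higher and 19 lower.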

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

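The tests named in this part were chosen after the values had been seen, except the permutation test of the A site window.

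The C-to-G rate in the A site window of the 5′ end went opposite ways in the fractions: it was above the other interior positions in both monosome libraries and below them in both disome libraries, a log2 difference of -1.30. The exact permutation p was 0.333, which 2 against 2 libraries cannot go below, so in effect the difference was not tested. With the peaks left out of the reference positions it was -0.76.

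The share of reads with a conversion, not scaled to length, also went opposite ways with footprint length. From the shortest to the longest footprints the share rose in both monosome libraries, from 5.80 to 6.52% and from 5.77 to 6.07%. In both disome libraries it was lower, 20.6 against 17.3% and 17.8 against 15.1%. Longer footprints hold more nucleotides that can convert, so the monosome rise can come from length alone. The opposite directions therefore need not mean opposite trends per nucleotide. The disome shares did not fall steadily: they were 22.7 and 18.4% at 60 nt and 19.9 and 17.5% at 65 nt, so most of the difference came from the 66-nt class. The log2 change from shortest to longest differed by -0.36 between disome and monosome libraries, and this difference was not tested beyond an exact permutation p of 0.333, the smallest possible.

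The comparisons of the report do not use the mismatches set aside as SNPs, and reads missing from both length lists are part of the total reads that rates are divided by. Whether conversions in those reads were counted is not given in the sources used here. SNPs made up 9.37% of all mismatches in monosome and 5.05% in disome libraries, and transitions were 75.7 ± 0.802% and 77.1 ± 0.0497% of them (SD, n = 2 each). The share set aside differed by type. It was 24.2% in monosome and 13.1% in disome libraries for G-to-A, 25.1 and 16.8% for A-to-G, and 14.4 and 7.80% for C-to-T. For C-to-G it was 1.46 and 0.612%, while T-to-A and T-to-G had higher shares in disome libraries. Reads in neither length list made up 2.85% of the monosome and 11.5% of the disome total. No conversion was listed beyond nucleotide 65 in disome footprints or 31 in monosome footprints.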

How the results depend on the processing

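Rates per nucleotide, per read in the length lists, over interior medians or outside the peaks, and edgeR, were chosen after seeing the data. Where a value moved, the cause was not tested unless stated.

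The excess of C-to-G in disome footprints kept its direction under all 12 alternatives, of which the replicate block cannot change it by construction. Its log2 difference of 2.05 fell to 1.01 per nucleotide, 0.49 per nucleotide outside the peaks and 0.45 for the median over positions, since these remove length or the peak by construction. Leaving out single libraries gave 1.83 to 2.27. The ratio of C-to-G to other types rose from a log2 of 3.50 to 4.69 against G-to-C alone. The peaks at nucleotides 18 and 48 stayed past the limma threshold under both other references, at log2 1.56 and 2.16 over G-to-C. G-to-C was low at monosome nucleotide 18 and raised at disome nucleotide 48, so these 2 values also reflect G-to-C.

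Types higher in disome footprints numbered 12 per read, 11 to 12 without single libraries, 6 per nucleotide (3 lower) and 4 after centring on the median (4 lower). Per nucleotide, counts without single libraries ran from 0 to 6 higher and from 0 to 3 lower, where a lone library is assumed to vary like the other fraction.

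Several types changed sign. Centring lowers all 12 types alike, so some fall below 0 by construction and these values rank types only: the log2 difference was -0.58 for G-to-C, -0.42 for G-to-T, -0.19 for A-to-C, -0.57 for T-to-A, -0.068 for T-to-C and -0.85 for T-to-G. Per nucleotide it was -0.37 for G-to-C, -0.21 for G-to-T, -0.36 for T-to-A and -0.64 for T-to-G. For the median over interior nucleotides it was -0.46 for G-to-C, -0.34 for G-to-T, -0.059 for A-to-C, -0.35 for A-to-G, -1.08 for A-to-T, -0.18 for T-to-A and -0.81 for T-to-G. Of the other values for single types and windows, 84 kept their direction and, where tested, their side of the threshold, some at a much smaller size such as C-to-G per nucleotide, while 12 moved and 7 lost the threshold.

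Combinations of nucleotide and type, 16 higher and 32 lower, were unstable. They were 3 and 14 over interior positions (fewer were tested), 21 and 19 after centring, and 2 to 39 and 3 to 96 without single libraries. Nucleotides above the interior median were 14 (mean reference) and 5 (over G-to-C) in place of 8 in monosomes. In disomes 51 lay below the mean reference, and over G-to-C 7 lay above and 7 below, in place of 13 and 19. The A site window difference of -1.30 was -1.03 and -1.37 with windows shifted by 1 nt toward the 5′ and 3′ end, and -0.76 outside the peaks.

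The libraries share replicate numbers, but the labels do not say that a number marks a shared culture. Over the 12 types, the log2 ratios of replicate 1 to 2 in monosomes and disomes correlated at Pearson r = 0.85, with 2 pairs only and types that are not independent. With the replicate number as a block, the C-to-G difference is 2.05 by construction, since the layout is balanced. In that fit limma called 12 types higher, but 0 combinations higher and 0 lower. Of the combinations, 105 had an unadjusted p under 0.05, against 112 without the block. Depth limits single nucleotides of rare types most in the disome libraries.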

Other observations

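The tests named in this part were chosen after the values had been seen, and no library of untreated cells was there to test a biological explanation.

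The other conversions from C also peaked in disome footprints near nucleotide 48, and C-to-T spread further downstream. At nucleotides 47 to 49 of disome footprints C-to-A stood at 5.80 ± 0.0863-fold and C-to-T at 7.30 ± 0.0142-fold their interior medians (SD, n = 2 each), beside 6.25 ± 0.250-fold for C-to-G. The ratio of C-to-A to C-to-G was 0.272 ± 0.00212 upstream (nucleotides 4 to 43), 0.245 ± 0.00686 in the peak and 0.302 ± 0.00489 downstream (nucleotides 51 to 55). The ratio of C-to-T to C-to-G was 0.259 ± 0.0314 upstream, 0.278 ± 0.0125 in the peak and 0.667 ± 0.0569 downstream. In monosome footprints the C-to-A ratio was 0.281 ± 0.0122 at nucleotides 4 to 15, 0.266 ± 0.0196 at the peak and 0.359 ± 0.0282 at nucleotides 21 to 25. The C-to-T ratio there was 0.301 ± 0.0288 at nucleotides 4 to 15, 0.325 ± 0.0358 at the peak and 0.640 ± 0.113 at nucleotides 21 to 25. Monosome C-to-T reached its summit at nucleotide 22, 4 nt past that of C-to-G. The causes of these downstream rises were not tested.

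By the median interior rate, which peaks and spikes hardly move, 5 of 12 types were higher and 7 lower in disome footprints, without a test. The median interior rate of C-to-T was 3.28 ± 0.654 per 10000 reads in disome and 3.22 ± 0.0586 in monosome footprints. A-to-T had 0.159 ± 0.00867 and 0.336 ± 0.00642, lower in disomes although its total per nucleotide was 1.96-fold higher. The disome median is the rate of nucleotides with only 7 and 6 conversions in replicates 1 and 2, such as nucleotide 19. Its small SD is therefore no measure of precision. G-to-A stood out the other way, with 1.48 ± 0.00588 in disome and 0.811 ± 0.0474 in monosome footprints (SD, n = 2 throughout). The disome value equals the rate of nucleotide 52, with 63 and 58 conversions, so its small SD is likewise no measure of precision. The monosome interior is shorter and leaves out nucleotide 29, where monosome G-to-A reached 3.43 per 10000 reads. Over the 29 nucleotides that both fractions share, the median log2 difference of G-to-A was 0.13. By limma, G-to-A was higher in disomes at 4 of them and lower at 3. The size of this difference thus depends on the nucleotides compared.

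The C-to-G peak of disome footprints lies 30 nt downstream of the monosome peak, while the mean monosome footprint is 30.5 nt long. In the windows of the leading ribosome, counted from the 3′ end, the A site window had the lowest rate, at 2.16-fold. The P site window had 2.72-fold and the E site window 2.67-fold. Windows counted from the 5′ and 3′ ends picked different sites for the monosome peak, largely because of how they were defined. The ranking of sites therefore depends on the site definition. These averages therefore assign the disome peak to no single site. An excess of C in the peak would lower the types that start from other bases. Over the 9 types not from C, the median log2 rate in the peak relative to the interior median was 0.43 and lay above 0 in both libraries, which argues against base composition as the whole cause. Fragments of the RNA that carries the spikes described next stay open: the log2 ratio of replicate 1 to 2 differed by 0.49 between the peak and the spikes, but C-to-G outside the peak had a ratio of 0.41, close to the 0.50 of the peak, and the spikes ranged from -0.59 to 0.26. Cleavage or size selection that depends on aza-C, and the treatment itself, were not tested.

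Conversions from A in disome footprints stood out at single nucleotides. A-to-G reached 15.9 ± 0.172 per 10000 reads at nucleotide 34, and A-to-T reached 10.8 ± 0.538 at nucleotide 58 and 8.81 ± 0.428 at nucleotide 37, against medians of 1.00 and 0.159. Monosome footprints also had raised nucleotides, lower and with more spread: A-to-T was 1.72 ± 0.769 at nucleotide 17 and 1.54 ± 0.562 at nucleotide 22, 5.18-fold and 4.65-fold the median, and A-to-G there 1.48-fold and 1.89-fold. In disomes the 4 highest A-to-T nucleotides held 66.7 ± 3.56% of all A-to-T conversions (SD, n = 2). Nucleotides 34, 37 and 58 are modified purines of tRNA in its usual numbering from the 5′ end, so tRNA fragments may be a source, but 2 of the 4 A-to-T spikes, 8.31 ± 1.93 at nucleotide 46 and 5.69 ± 1.63 at nucleotide 44, match no listed site. Of 7 listed sites, 4 were listed after their spikes had been seen and cannot test this. They are A at nucleotides 34, 37 and 58, and G at nucleotide 26, where conversions from G stood at 2.92-fold the median. The other 3 averaged 1.09-fold the median (one-sided permutation p = 0.305 over 100000 random sets), so tRNA fragments stay open. A single sequence variant is argued against at nucleotides 37 and 58, where the less frequent of A-to-G and A-to-T still made up at least 36.9% of conversions from A, but at nucleotide 34 the other bases made up at most 10.8%, so a variant and a modified base cannot be told apart there.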
